A study of Homo sapiens with 8 samples.

How the data were processed

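The series holds 8 RNA-seq libraries of the human line AC16 in 4 groups of 2: glucose 25 mM, 25 to 50 mM, 5 mM and 5 to 50 mM. Per the labels, cells were kept at 5 or 25 mM for at least 3 passages, the rise to 50 mM lasted 24 h, and total RNA was extracted with TRIzol. The submitters' processing notes name STAR and the hg38 build, with no version of STAR. The authors deposited 2 tables of RPKM values (reads scaled to gene length and library depth), 1 for each starting glucose, with a column per library and a row per gene; the counting tool, the annotation and the gene lengths are not stated. Each table lists 19479 genes by Entrez number and symbol, of which 16297 are above 0 in at least 1 library and 3182 are at 0 in all 8.

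Whole reads were recovered from the RPKM values to learn the depth. A library total and a gene length were sought that turn every value into a whole number of reads within 0.01, and 100% of the genes above 0 came out whole, with whole gene lengths for 99.87% of the genes above 0 in all libraries. Library totals ran from 21538898 to 27372851 reads, with 99.82% to 99.85% of them in listed genes, and the highest upper quartile of RPKM was 1.061 times the lowest. On 5000 simulated genes the recovery gave exact reads for 99.6% of genes. The Entrez numbers were matched to a RefSeq gene table for coordinates (19432 matched) and to transcript GC content (19183 with a value); 19132 are protein coding. Gene symbols are printed as the tables give them. The libraries of each group differed by more than counting error over all genes, so no group holds plain copies of 1 library. Separate preparations or runs of 1 RNA sample are not excluded by this. Chi-square per degree of freedom was 6.73 at 25 mM and 7.84 at 25 to 50 mM. It was 16.55 at 5 mM and 2.6 at 5 to 50 mM. Among well-covered genes the median dispersion, the spread beyond counting error, was -2e-05 at 5 to 50 mM and 0.00237 at 5 mM. The typical such gene at 5 to 50 mM thus varied no more than by counting error.

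Values were taken as log2(RPKM + 1). Genes with at least 1 RPKM in at least 2 of the fitted libraries were tested with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested in a comparison and a threshold of 0.05. The comparisons of 25 to 50 mM with 25 mM and of 5 to 50 mM with 5 mM were each fitted on their own 4 libraries. The difference between these responses and the comparison of the 25 mM with the 5 mM cultures were fitted on all 8 libraries with 1 shared spread; the latter was to be run only if the upper quartiles differed by less than 1.5 times. Within their own 4 libraries the rises could not be fitted with replicate number as a block, because the groups share only 1 replicate number. A block over all 8 libraries, which takes a replicate number to mean the same in both tables, left 2 residual degrees of freedom and was added later. The test was tried on simulated data with 200 changed genes: at 1.5-fold it recovered 98.8% in a design like the 25 mM one and 96% in one like the 5 mM one, with 11.6 and 11.8 false calls per run. The depth therefore did not limit changes of this size in genes past the filter, as far as the simulated spread holds for the libraries.

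A set of 35 gene lists, the rule for named genes, the filter, the tests and most alternatives were fixed before the data were examined. No gene of 2 of these lists is in the tables, and 33 were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 33 lists of a comparison. This test compares a list with the other genes, whose median log2 change was -0.035 from 25 mM and -0.028 from 5 mM. With an estimated correlation camera also uses the few residual degrees of freedom of the fit, which raises p-values by itself. From 5 to 50 mM the hyperosmotic list had an estimated correlation of 0.011, close to the preset one. Its unadjusted camera p still went from 6.14e-05 to 0.0575. A call lost in this repeat therefore does not show that correlation among members produced it. The rule names 16 focus genes in any case, up to 8 genes per direction with the largest change among called genes with a mean of at least 5 RPKM and groups that do not overlap (5 per direction for the other comparisons), and up to 4 members of each list that passed. Part of the named genes are printed, and 2 were left out of them altogether.

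Alternatives were a pseudocount of 0.1 or 0.5, no filter, a mean of at least 5 RPKM, median centring, quantile normalization, limma without trend or with robust estimation, other thresholds, a joint fit, and leaving out each library in turn. Count tests planned for the case that whole reads could be recovered were not run, since the rules of this work allow them for no RPKM values, and voom took their place. Added after the data were seen were the replicate block over all 8 libraries, a GC correction (a spline with 5 degrees of freedom on transcript GC content, per library), voom on the recovered reads, fits with neither library that showed a GC trend, the 4 control libraries alone, and the planned list and gene alternatives for the other 2 comparisons. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Mitochondrially encoded transcripts and nuclear-retained RNAs, which the tables do not list, were left out.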

Results

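RNA was sequenced from AC16 cells, a dividing human line made by fusing adult ventricular cardiomyocytes with transformed fibroblasts. The 8 total RNA libraries fall into 4 groups of 2. Cells were kept at 5 mM or at 25 mM glucose. For each of these, a further group was raised to 50 mM for 24 h by adding 45 mM or 25 mM glucose. The study's title asks about ERK1/2 and the co-activators YAP1 and TAZ in high glucose. These 8 libraries include no cells given an ERK inhibitor and no osmotic control. In the 25 mM group, replicates 1 and 3 had 26673336 and 27168172 reads. In the 25 to 50 mM group, replicates 2 and 3 had 24579003 and 24983510 reads. In the 5 mM group, replicates 1 and 3 had 21538898 and 27372851 reads, and in the 5 to 50 mM group replicates 1 and 2 had 23347415 and 23231096 reads. A gene of 1 kb therefore needed 0.11 to 0.139 RPKM (reads scaled to gene length and library depth) to be covered by 3 reads. Values are group means ± SD with n = 2 libraries per group, and folds are those of the fitted log2(RPKM + 1) values. The series describes the replicates as technical, so every p-value below measures the spread between libraries, which may be technical only, and not the spread between independent cultures.

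Most listed markers of cardiomyocytes were low, with exceptions. TNNT2, cardiac troponin T, was at 0.0614 ± 0.0296 RPKM at 25 mM and at 0 in both libraries at 5 mM, under the 3-read floor. ATP2A2, the calcium pump of the sarcoplasmic reticulum, was at 200.3 ± 0.0535 RPKM at 25 mM and 205 ± 10.8 RPKM at 5 mM, and GJA1, a gap junction protein, at 108 ± 4.39 and 98.8 ± 6.57 RPKM. Of 23 listed cardiomyocyte markers, 3 passed the filter on low values in the comparison that started from 25 mM and 5 in the one that started from 5 mM. Of 15 listed fibroblast markers, 13 and 14 passed this filter. In both comparisons 0 of the cardiomyocyte markers passed the limma test over all genes tested. Adjusted over the list alone, 0 passed from 25 mM and 1 was higher from 5 mM. At an unadjusted p under 0.05 there was 1 lower member from 25 mM and there were 2 higher ones from 5 mM, and voom called 0.

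The first comparison asked how cells kept at 5 mM glucose, near the fasting level in blood, respond to 50 mM. Among targets of YAP1 and TAZ, 4 of 22 rose and 18 did not pass. CTGF (Entrez Gene 1490, now CCN2, chromosome 6, 131948176 to 131951372 in hg38), a secreted matrix protein, rose 2.12-fold, from 138 ± 5.19 to 292.5 ± 13.7 RPKM. ANKRD1 (Entrez Gene 27063, chromosome 10, 90912096 to 90921087), a stretch-responsive muscle ankyrin repeat protein, rose 2.26-fold, from 16.3 ± 1.03 to 38.1 ± 3.76 RPKM. CYR61 (Entrez Gene 3491, now CCN1) rose 1.40-fold, from 795 ± 3.38 to 1113 ± 11.5 RPKM, and TGFB2, a growth factor that drives fibrosis, 1.57-fold, from 18.9 ± 0.0973 to 30.3 ± 0.929 RPKM. The transcripts of the co-activators themselves did not pass: YAP1 had a log2 change of -0.10 (SE 0.06, adjusted p = 0.604) and WWTR1, which encodes TAZ, one of -0.15 (SE 0.07, adjusted p = 0.558).

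Of 22 genes of the YAP1/TAZ target signature, 4 rose, 0 fell and 18 did not pass over all genes tested; adjusted over the list alone, 6 rose and 1 fell. The list as a whole rose against the other genes (median log2 change 0.13, adjusted p = 3.68e-06 by limma's camera with a preset correlation). This call was lost at adjusted p = 0.271 with an estimated correlation, which also uses fewer degrees of freedom. Among 27 components of the Hippo pathway, the kinase cascade that restrains YAP1, limma called 0. The list's median log2 change was -0.04, with a positive test direction against the other genes (adjusted p = 0.975). At an unadjusted p under 0.05, 2 were higher and 2 lower, voom called 0, and 0 passed adjusted over the list alone.

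The ERK genes fixed for this comparison gave no call. MAPK3, which encodes ERK1, had a log2 change of -0.02 (SE 0.06, adjusted p = 0.935). DUSP6, an ERK phosphatase induced by ERK itself, was at 19.5 ± 3.47 RPKM at 5 mM and 17.4 ± 1.37 RPKM after the rise (log2 change -0.15, SE 0.14, adjusted p = 0.773), and SPRY4, a feedback inhibitor, at 12 ± 2.27 and 13.5 ± 1.74 RPKM (adjusted p = 0.782). EGR1, an immediate early gene, had a log2 change of -0.19 (SE 0.10, adjusted p = 0.599). Outside the fixed genes DUSP1, an immediate early MAP kinase phosphatase chosen after its values were seen, rose 1.62-fold, from 41.4 ± 2.08 to 67.8 ± 2.81 RPKM (adjusted p = 0.0411). Of 22 tested ERK pathway output genes, limma called 0 over all genes tested, 2 up and 1 down adjusted over the list alone, 3 up and 1 down at an unadjusted p under 0.05, and voom called 0. The list had a median log2 change of -0.06, with a positive test direction against the other genes (adjusted p = 0.999). The 22 ERK pathway components gave 0 calls by limma, 0 adjusted over the list alone and 0 by voom. Of these, 1 was lower at an unadjusted p under 0.05 (list adjusted p = 0.583).

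**Figure D1:**
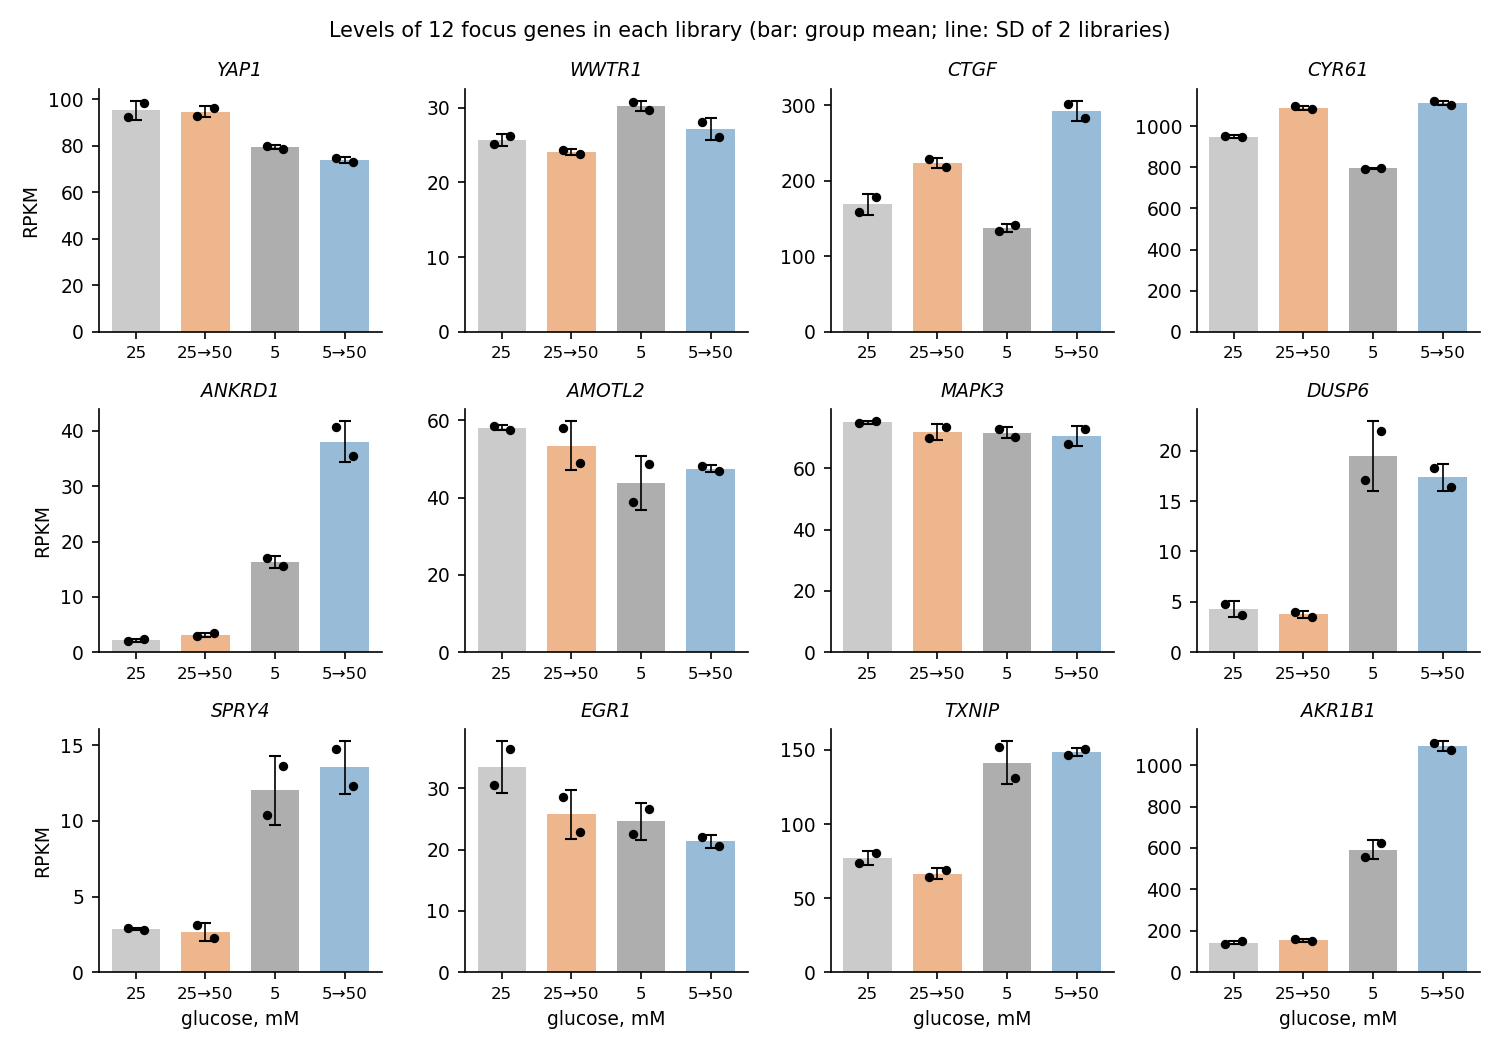
RPKM of 12 focus genes in each library, by glucose in mM; points are libraries, bars are group means and lines are the SD of 2 libraries, each axis starting at 0. CTGF reached 292.5 RPKM and ANKRD1 38.1 RPKM after 5 to 50 mM, while YAP1 was at 79.3 RPKM at 5 mM and 73.9 RPKM after the rise.

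Interferon-stimulated genes formed the list that rose most from 5 to 50 mM. IFIT2 (Entrez Gene 3433, chromosome 10, 89302046 to 89309271), an antiviral effector, rose 1.89-fold, from 98.1 ± 0.129 to 187 ± 7.38 RPKM. DDX58 (now RIGI), the cytosolic RNA sensor, rose 1.67-fold, from 59.8 ± 1.11 to 100.5 ± 3.7 RPKM, and IFIT1 1.80-fold, from 153 ± 2.91 to 276.5 ± 23.5 RPKM. CXCL10, an interferon-induced chemokine, rose 2.46-fold, from 10.0 ± 0.935 to 26.2 ± 2.36 RPKM. All 19 listed interferon response genes had higher fitted values after the rise. Of them, 6 passed over all genes tested, 13 did not, and 14 rose adjusted over the list alone (median log2 change 0.48, adjusted p = 1.86e-22; adjusted p = 0.271 with an estimated correlation). The libraries of this comparison differed little in this list: its median was 0.018 log2 higher in 5 mM replicate 1 than in replicate 3 and 0.08 higher in 5 to 50 mM replicate 2 than in replicate 1. Reads of the IFIT genes, which are close paralogs, may be shared among them.

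Among cytokine genes, CCL2, a monocyte chemoattractant, rose 1.54-fold, from 85.6 ± 1.36 to 132.5 ± 0.241 RPKM, and IL6 1.76-fold, from 48.3 ± 3.2 to 85.9 ± 7.49 RPKM. Of 18 tested NF-kB and cytokine response genes, 2 rose, 0 fell and 16 did not pass, and 3 rose adjusted over the list alone (median log2 change 0.18, adjusted p = 8.15e-06; adjusted p = 0.462 with an estimated correlation). PTGS2, the inducible cyclooxygenase, had a log2 change of 0.59 (SE 0.12, adjusted p = 0.192) and CXCL8 one of 0.37 (SE 0.10, adjusted p = 0.309).

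Some matrix, actin and cardiac stress genes rose and most did not pass. EDN1 (Entrez Gene 1906, chromosome 6, 12230516 to 12297194), the vasoconstrictor endothelin, rose 2.38-fold, from 18.3 ± 0.734 to 45.0 ± 4.55 RPKM. TNC, the matrix protein tenascin C, rose 1.60-fold, from 127 ± 1.75 to 205 ± 6.82 RPKM, and THBS1 1.55-fold. TPM1, a tropomyosin, rose 1.68-fold, from 390 ± 0.63 to 654 ± 8.93 RPKM, and TAGLN, an actin-binding protein of smooth muscle, 1.43-fold. RCAN1, a calcineurin regulator, rose 1.67-fold, from 26.9 ± 0.178 to 45.6 ± 0.293 RPKM. Of 29 extracellular matrix and fibrosis genes, 5 rose and 24 did not pass, and adjusted over the list alone 11 rose and 1 fell (median log2 change 0.18, adjusted p = 1.79e-09; adjusted p = 0.271 with an estimated correlation). Of 20 actin cytoskeleton and SRF targets, 2 rose and 18 did not pass, and 7 rose adjusted over the list alone (median log2 change 0.18, adjusted p = 1.82e-11; adjusted p = 0.271 with an estimated correlation). Of 5 tested cardiac stress and hypertrophy markers, 2 rose, 3 did not pass, and 3 rose adjusted over the list alone (median log2 change 0.39, adjusted p = 0.000131; adjusted p = 0.271 with an estimated correlation). These 2 calls were RCAN1 and ANKRD1, which is also among the YAP1/TAZ calls above. Other lists share members too: CTGF is in the YAP1/TAZ and matrix lists, and ACTA2 and CNN1 are in the actin and smooth muscle lists. Their calls are therefore not separate responses. NPPA had a log2 change of 0.14 (SE 0.10, adjusted p = 0.705), and NPPB, at 0.0988 to 0.371 RPKM in the 4 group means, stayed under the filter.

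Metabolic and osmotic stress genes included AKR1B1 (Entrez Gene 231, chromosome 7, 134442350 to 134459239), the aldose reductase that turns glucose into sorbitol, which rose 1.84-fold, from 592 ± 47.4 to 1092 ± 24.7 RPKM. SGK1, a kinase induced by salt and glucocorticoids, rose 1.82-fold, from 30.7 ± 0.779 to 56.8 ± 2.48 RPKM, while SLC5A3, the osmotically regulated inositol transporter, had a log2 change of 0.31 (SE 0.11, adjusted p = 0.436). Of 14 tested hyperosmotic response genes, 2 rose and 12 did not pass, and adjusted over the list alone 5 rose and 1 fell (median log2 change 0.13, adjusted p = 0.000203; adjusted p = 0.271 with an estimated correlation). AKR1C1, a reductase that shares reads with its paralogs, rose 2.27-fold, and ME1, the cytosolic malic enzyme, 1.56-fold. They were the 2 calls among 20 NRF2 antioxidant genes, 18 of which did not pass. Likewise 2 rose adjusted over the list alone (median log2 change 0.06, adjusted p = 0.0319; adjusted p = 0.497 with an estimated correlation). Cholesterol synthesis genes rose as a list of 24 (median log2 change 0.16, adjusted p = 1.39e-06; adjusted p = 0.271 with an estimated correlation). Their calls were 0 by limma over all genes tested, 9 up adjusted over the list alone, 12 up and 1 down at an unadjusted p under 0.05, and 0 by voom. SQLE, an oxygen-dependent enzyme of the pathway, had a log2 change of 0.25 (SE 0.06, adjusted p = 0.245) and STARD4, a sterol carrier, 0.36 (SE 0.06, adjusted p = 0.161).

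The thioredoxin-binding TXNIP and its relative ARRDC4, textbook targets of the glucose sensor MondoA, did not pass. TXNIP was at 141 ± 14.6 RPKM at 5 mM and 148 ± 2.86 RPKM after the rise (log2 change 0.07, SE 0.08, adjusted p = 0.829), and ARRDC4 had a log2 change of -0.21 (SE 0.14, adjusted p = 0.689). The 10 tested MondoA/ChREBP targets gave 0 calls by limma, 0 adjusted over the list alone, 1 lower at an unadjusted p under 0.05 and 0 by voom (list adjusted p = 0.731, with a median log2 change of 0.02, a mean of -0.06 and a negative test direction). The 22 glycolysis genes gave 0 calls by limma, 1 down adjusted over the list alone, 4 down at an unadjusted p under 0.05 and 0 by voom (median log2 change -0.07, adjusted p = 0.227).

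The G2/M and p53 lists fell. All 24 G2/M cell cycle genes had lower fitted values after the rise (median log2 change -0.14, adjusted p = 6.29e-05; adjusted p = 0.497 with an estimated correlation). Limma called 0 of them over all genes tested, 0 adjusted over the list alone and 7 at an unadjusted p under 0.05, with 0 by voom. NUSAP1, a spindle protein, had a log2 change of -0.27 (SE 0.05, adjusted p = 0.194) and TOP2A one of -0.26 (SE 0.08, adjusted p = 0.34). The other cell cycle list, G1/S and DNA replication, did not pass (22 tested, median log2 change -0.04, adjusted p = 0.256), with 0 calls by limma over all genes tested, 0 adjusted over the list alone, 1 up and 4 down at an unadjusted p under 0.05 and 0 by voom. The 20 p53 targets had a median log2 change of -0.19 (adjusted p = 0.000131; adjusted p = 0.462 with an estimated correlation). Single members gave 0 calls by limma over all genes tested, 1 down adjusted over the list alone, 8 down at an unadjusted p under 0.05 and 0 by voom. MDM2, the ubiquitin ligase that degrades p53, was at 40.7 ± 1.12 RPKM at 5 mM and 29.04 ± 0.611 RPKM after the rise (log2 change -0.47, SE 0.07, adjusted p = 0.0865).

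A list set to watch library quality moved in this comparison too. Replication-dependent histones (13 tested) rose as a list (median log2 change 0.39, adjusted p = 0.000775; adjusted p = 0.497 with an estimated correlation). There were 0 calls by limma over all genes tested, 6 up and 2 down adjusted over the list alone, the same numbers at an unadjusted p under 0.05, and 0 by voom. Their median was above those of the YAP1/TAZ, matrix and actin lists, and a part of RNA or library quality in the list changes was not excluded. The other such list, cytosolic ribosomal proteins, did not pass (adjusted p = 0.219), with 0 calls by limma over all genes tested, 0 adjusted over the list alone, 1 down at an unadjusted p under 0.05 and 0 by voom. These short histone genes are near copies, and reads may be shared between them. The 14 tested fibroblast markers rose as a list (median log2 change 0.06, adjusted p = 0.00424; adjusted p = 0.393 with an estimated correlation). They gave 0 calls by limma over all genes tested, 4 adjusted over the list alone, 5 at an unadjusted p under 0.05 and 0 by voom. PDGFRB had a log2 change of 0.43 (SE 0.08, adjusted p = 0.166). The 7 smooth muscle and pericyte markers rose as a list (median log2 change 0.05, adjusted p = 0.0164; adjusted p = 0.393 with an estimated correlation). Their calls were 0 by limma over all genes tested, 2 adjusted over the list alone, 2 at an unadjusted p under 0.05 and 1 by voom. MYOCD, the co-activator of smooth muscle genes, was at 0.556 ± 0.0331 and 2.15 ± 0.192 RPKM (log2 change 1.01, SE 0.12, adjusted p = 0.0565).

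Over all 11849 genes tested from 5 to 50 mM, 37 rose and 2 fell by limma, 8 of them by at least 2-fold, and 1246 had an unadjusted p under 0.05 (611 up, 635 down). PRSS35 (Entrez Gene 167681, chromosome 6, 83512534 to 83525704), a protease-like secreted protein, rose 3.33-fold, from 3.79 ± 0.595 to 14.9 ± 0.444 RPKM. RAB27B (Entrez Gene 5874, chromosome 18, 54717857 to 54895516), a GTPase of vesicle secretion, fell by 0.67 on the log2 scale, from 35.9 ± 1.35 to 22.2 ± 0.263 RPKM. The other gene that fell was SLC16A6, a monocarboxylate transporter, from 6.17 ± 0.213 to 2.5 ± 0.0668 RPKM. It lies under the level set for naming and was chosen after its values were seen. With 1 library left out, the count depended on which group kept 2 libraries. Limma called 805 genes without 5 mM replicate 1, 560 without 5 mM replicate 3, 4 without 5 to 50 mM replicate 1 and 0 without 5 to 50 mM replicate 2. In these fits the spread came only from the group that kept 2 libraries, and the lone library was assumed to vary like it. Without a 5 mM library that group was 5 to 50 mM, with a chi-square per degree of freedom of 2.6 between its libraries. Without a 5 to 50 mM library it was 5 mM, at 16.55. Without trend or without the filter limma called 0, and voom called 49 (48 up, 1 down). After the GC correction limma called 147 up and 22 down. A joint fit of all 8 libraries called 105 up and 25 down, among them 29 of the 39, and 0 with the replicate number as a block (482 higher and 401 lower at an unadjusted p under 0.05). In the blocked fit, which left 2 residual degrees of freedom, CTGF had a log2 change of 1.11 (SE 0.09, adjusted p = 0.0665), against 1.08 (SE 0.07, adjusted p = 0.00156) without the block.

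The second comparison asked the same of cells kept at 25 mM, the glucose of standard growth medium, where the added glucose was 25 mM in place of 45 mM. TAGLN (Entrez Gene 6876, chromosome 11, 117199294 to 117207465) rose 1.64-fold, from 530 ± 14.7 to 869 ± 9.8 RPKM (log2 change 0.71, SE 0.04, adjusted p = 0.022). It was the 1 gene called among 11422 tested, with 0 down; at an unadjusted p under 0.05, 320 were higher and 737 lower, and voom called 7 up and 0 down. Other matrix and actin genes had higher values without passing: TPM1 was at 399.6 ± 6.5 and 527 ± 13.5 RPKM (adjusted p = 0.158) and FN1, fibronectin, at 898 ± 68.3 and 1216 ± 3.76 RPKM (adjusted p = 0.227).

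All 20 actin cytoskeleton and SRF targets had higher fitted values at 50 mM; 1 rose and 19 did not pass. Adjusted over the list alone, 9 rose (median log2 change 0.15, adjusted p = 7.73e-16; adjusted p = 0.558 with an estimated correlation). The 29 extracellular matrix and fibrosis genes rose as a list (median log2 change 0.13, adjusted p = 4.31e-13; adjusted p = 0.558 with an estimated correlation). Single members gave 0 calls by limma over all genes tested, 12 up adjusted over the list alone, 15 up at an unadjusted p under 0.05 and 3 by voom. The 5 cardiac stress and hypertrophy markers (median log2 change 0.23, adjusted p = 0.0369; adjusted p = 0.558 with an estimated correlation) gave 0 calls by limma over all genes tested, 3 up adjusted over the list alone and at an unadjusted p under 0.05, and 0 by voom. This list passed neither with median centring nor with the GC correction (adjusted p = 0.14). The 7 smooth muscle and pericyte markers (median log2 change 0.05, adjusted p = 0.0285; adjusted p = 0.633 with an estimated correlation) gave 0 calls by limma over all genes tested, 2 up adjusted over the list alone and at an unadjusted p under 0.05, and 0 by voom, and did not pass with median centring (adjusted p = 0.075). ACTA2, smooth muscle actin, was at 6.78 ± 0.0972 and 9.41 ± 0.385 RPKM (adjusted p = 0.444).

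The YAP1/TAZ target signature rose as a list against the other genes, by less than from 5 mM (median log2 change 0.03, adjusted p = 0.000443; adjusted p = 0.558 with an estimated correlation). Of its 22 members, limma called 0 over all genes tested, 5 up adjusted over the list alone, 8 up at an unadjusted p under 0.05, and voom 0. CTGF was at 169 ± 13.6 and 223.5 ± 6.68 RPKM (log2 change 0.40, SE 0.06, adjusted p = 0.321), CYR61 at 949 ± 5.53 and 1090 ± 9.84 RPKM (log2 change 0.20, SE 0.04, adjusted p = 0.444) and ANKRD1 at 2.18 ± 0.273 and 3.13 ± 0.41 RPKM (log2 change 0.37, SE 0.13, adjusted p = 0.502). YAP1 had a log2 change of -0.01 (SE 0.05, adjusted p = 0.958), a sign that turned with median centring, and WWTR1 one of -0.10 (SE 0.06, adjusted p = 0.627). The list did not pass without 25 to 50 mM replicate 2 (adjusted p = 0.115).

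The fixed ERK genes gave no call here either. MAPK3 had a log2 change of -0.06 (SE 0.05, adjusted p = 0.682), DUSP6 one of -0.13 (SE 0.13, adjusted p = 0.751), and EGR1 one of -0.37 (SE 0.13, adjusted p = 0.502). Of 20 tested ERK pathway output genes, limma called 0 over all genes tested and 0 adjusted over the list alone, 3 were higher and 3 lower at an unadjusted p under 0.05, and voom called 0 (median log2 change -0.02 with a positive test direction against the other genes, adjusted p = 0.335). The 27 Hippo pathway components gave 0 calls by limma, 0 adjusted over the list alone, 1 higher and 1 lower at an unadjusted p under 0.05, and 0 by voom (median log2 change -0.004 with a positive test direction, adjusted p = 0.361). TXNIP was at 77.1 ± 4.56 RPKM at 25 mM and 66.6 ± 3.44 RPKM at 50 mM (log2 change -0.21, SE 0.07, adjusted p = 0.502), and AKR1B1 had a log2 change of 0.11 (SE 0.06, adjusted p = 0.581).

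The remaining lists that passed from 25 to 50 mM had 0 calls by limma over all genes tested and 0 by voom. Both lists set to watch library quality, histones and ribosomal proteins, were among them. The actin, matrix and YAP1/TAZ list changes of this comparison stand beside theirs, and a part of RNA or library quality was not excluded. Replication-dependent histones (9 tested) rose (median log2 change 0.31, adjusted p = 2.89e-05; adjusted p = 0.558 with an estimated correlation). Of these, 2 were up adjusted over the list alone and 3 up at an unadjusted p under 0.05. The 14 tested hyperosmotic response genes rose (median log2 change 0.10, adjusted p = 0.00208; adjusted p = 0.558 with an estimated correlation). Of these, 1 was up adjusted over the list alone and 4 up at an unadjusted p under 0.05. SGK1 was at 21.4 ± 0.577 and 27.0 ± 0.809 RPKM (adjusted p = 0.444). The 46 cytosolic ribosomal proteins (median log2 change 0.03, adjusted p = 0.0036) and 15 heat shock genes (median log2 change 0.06, adjusted p = 0.00459) rose against the other genes, each at adjusted p = 0.558 with an estimated correlation. They had 0 calls adjusted over the list alone, and 2 and 1 members higher at an unadjusted p under 0.05. G2/M cell cycle genes fell: 23 of 24 had lower fitted values (median log2 change -0.09, adjusted p = 0.0172; adjusted p = 0.633 with an estimated correlation). Adjusted over the list alone 0 passed, and 5 were lower at an unadjusted p under 0.05. The 17 tested interferon response genes did not pass (median log2 change -0.23, adjusted p = 0.0663), with 0 calls by limma over all genes tested, adjusted over the list alone, at an unadjusted p under 0.05 and by voom. Its sign rests on 25 mM replicate 3, where the list lay 0.525 log2 higher than in replicate 1: against replicate 1 alone the median was 0.059. TAGLN did not pass without 25 mM replicate 1 or without replicate 3 (adjusted p up to 0.976), although its log2 change stayed between 0.685 and 0.742 with 1 library left out. In the joint fit with the replicate number as a block, TAGLN had a log2 change of 0.70 (SE 0.06, adjusted p = 0.45), and limma called 0 genes, with 177 higher and 338 lower at an unadjusted p under 0.05. Without 25 to 50 mM replicate 2, the 25 to 50 mM group rests on replicate 3 alone. In that library the bin of genes richest in GC lay at a median of -0.30 log2 against replicate 2. Such a fit therefore mixes a library trend with the rise.

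**Figure D2:**
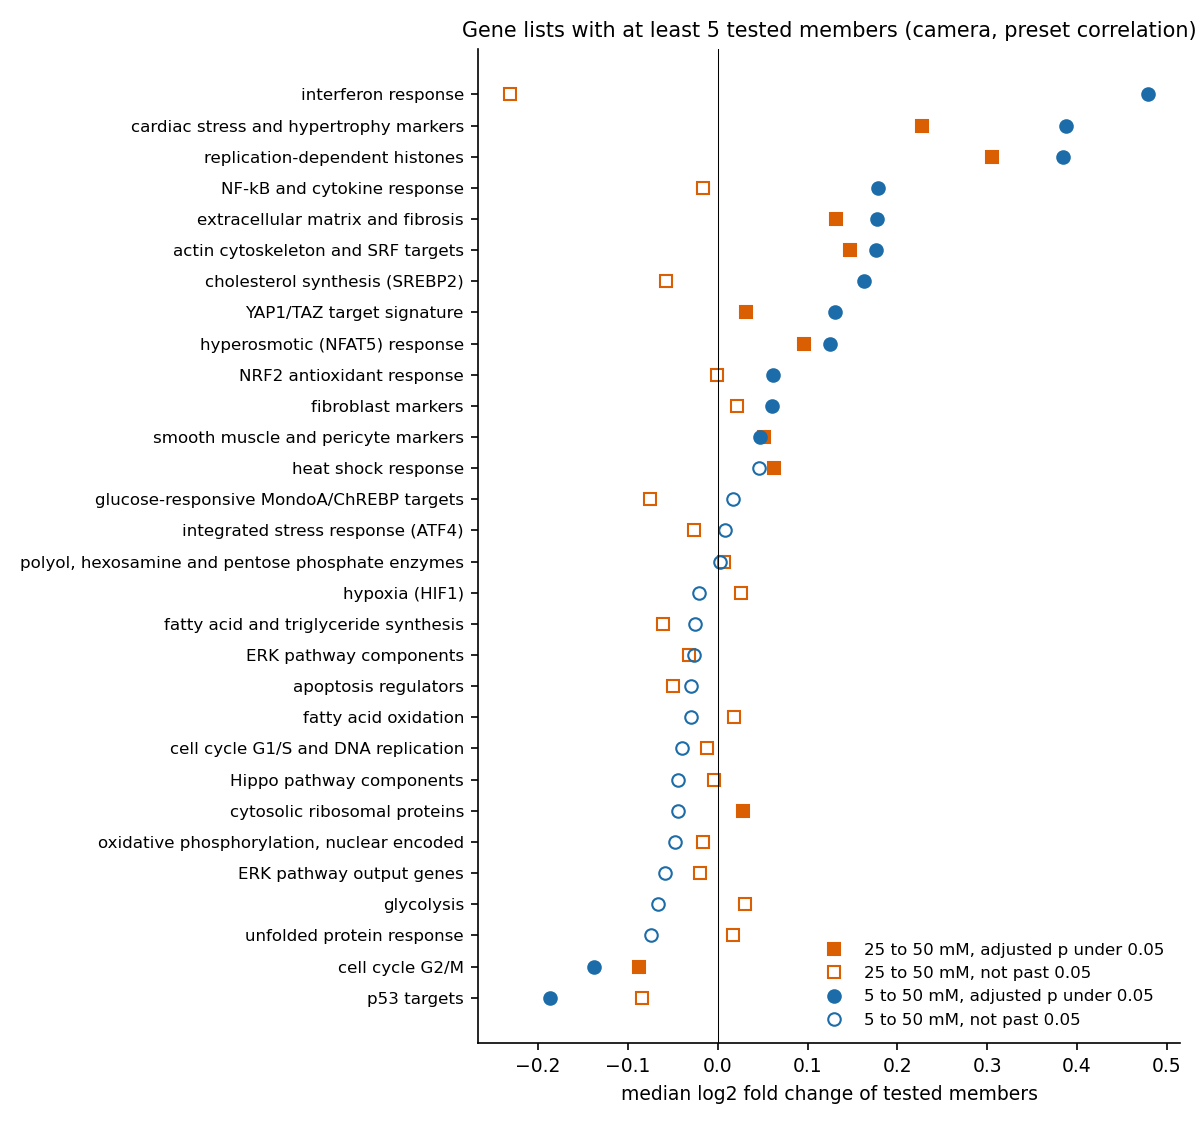
Median log2 fold change of the tested members of each gene list with at least 5 tested members, for 25 to 50 mM (squares) and 5 to 50 mM (circles); filled marks passed limma's camera at an adjusted p under 0.05 with a preset correlation. The interferon list lay at 0.48 from 5 mM and at -0.23 from 25 mM, or at 0.059 against 25 mM replicate 1 alone.

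The third question was whether the responses from 25 and from 5 mM differed. They differ in starting glucose, in added glucose (25 against 45 mM) and in table, so a difference cannot be assigned to any one of these. In a joint fit of all 8 libraries, 3 of 11941 genes differed between the responses. SERPINB2 (Entrez Gene 5055, chromosome 18, 63887705 to 63903888), an inhibitor of urokinase, was at 97.4 ± 3.91 and 147.5 ± 1.75 RPKM from 25 mM but at 266 ± 11 and 242 ± 4.33 RPKM from 5 mM, a difference of 0.73 log2 (SE 0.07, adjusted p = 0.0361). PRSS35 was at 1.254 ± 0.322 and 0.91 ± 0.102 RPKM from 25 mM against its rise from 5 mM, a difference of -1.97 log2 (SE 0.19, adjusted p = 0.0361). RANBP3L, chosen after its values were seen, reached 3.41 ± 0.0874 RPKM from 0.531 ± 0.018 RPKM at 5 mM. From 25 mM it was at 0.0575 ± 0.0155 and 0.0755 ± 0.0717 RPKM, means under the 3-read floor of a 1 kb gene, and stayed under the filter. The difference for RANBP3L was -1.50 log2 (adjusted p = 0.0361). CTGF and ANKRD1 did not pass this test (differences of -0.68, adjusted p = 0.228, and -0.80, adjusted p = 0.388), nor did AKR1B1 (-0.78, adjusted p = 0.126). Of the genes called from 5 mM, PRSS35 and RANBP3L alone passed it.

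The interferon response list was lower in the 25 to 50 mM response (median difference -0.83 log2, adjusted p = 2.6e-15; adjusted p = 0.328 with an estimated correlation). Of its 19 members, 0 were called by limma over all genes tested and 12 were down adjusted over the list alone. Without 25 mM replicate 3 the median difference was -0.479. Cholesterol synthesis genes (median difference -0.22, adjusted p = 1.16e-09; adjusted p = 0.0639 with an estimated correlation) and the YAP1/TAZ target signature (median difference -0.13, adjusted p = 0.0097; adjusted p = 0.328 with an estimated correlation) were lower as well. Of their 24 and 22 members, 8 and 3 were down adjusted over the list alone and 0 called over all genes tested. When neither library with a GC trend was used, 6 of 10 list calls for this difference stayed. Those of the YAP1/TAZ signature and of cardiac stress markers (each adjusted p = 0.162), of NF-kB and cytokine genes (adjusted p = 0.535) and of G1/S genes (adjusted p = 0.641) were lost. Over the 11352 genes tested in both comparisons, the changes had a Pearson correlation of 0.297 and a Spearman correlation of 0.305 across genes, which are not independent replicates. TAGLN was the 1 gene called up in both, against 0.0029 expected if every gene were equally likely to be called (Fisher's exact test, two-sided p = 0.00291). With only 1 gene called from 25 mM, this p restates the expected number and says little about a shared response. Of 34 genes called from 5 mM and tested from 25 mM, 22 had the same sign from 25 mM, beside 63.4% of all genes tested in both. With the same sign and an unadjusted p under 0.05 by limma from 25 mM there were 17 of the 34. Of all 11422 genes tested from 25 mM, 1057 had such a p in either direction. The 33 of the 34 that rose from 5 mM had a median log2 change of 0.73 there, where they were selected, and 0.17 from 25 mM. The Pearson correlation depended on the 5 mM libraries: it was -0.078 without replicate 3 and 0.541 without replicate 1. Both 5 mM replicate 1 and 25 to 50 mM replicate 3 were low in GC-rich transcripts. These trends oppose each other in the 2 responses when replicate 1 is the only 5 mM control, and align when it is left out. The correlation and the share of equal signs may thus hold library GC trends, by an amount not tested. For the difference between the responses, 0 genes passed by limma with a pseudocount of 0.1 and 0 by voom, against 721 at an unadjusted p under 0.05. With the replicate number as a block 0 passed by limma, with PRSS35 at -2.07 log2 (SE 0.18, adjusted p = 0.358).

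**Figure D3:**
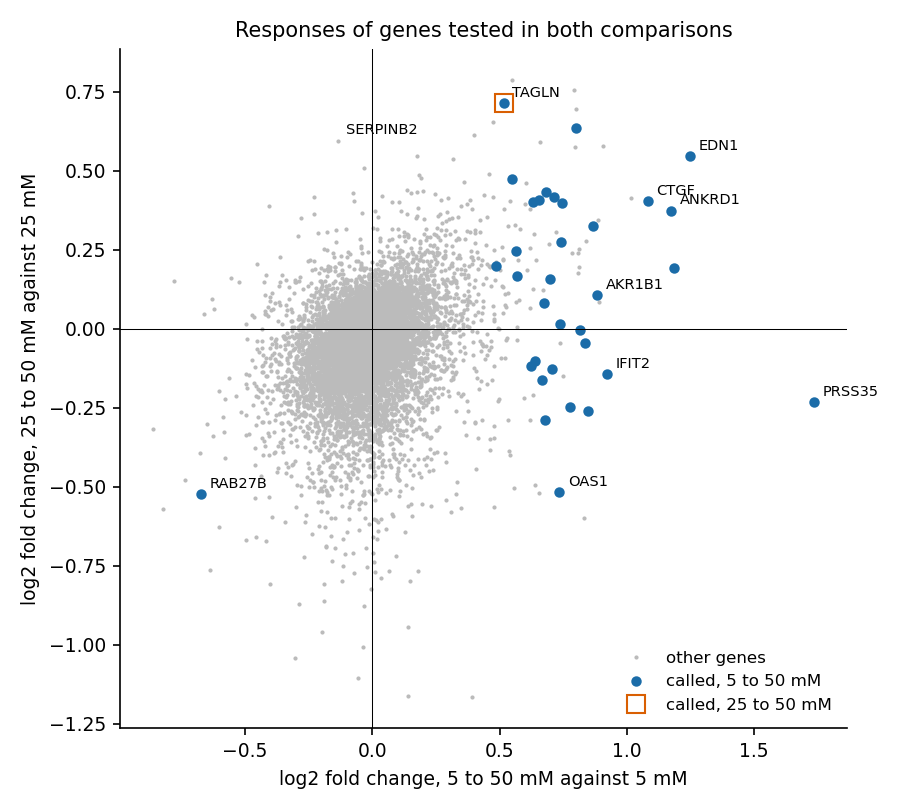
Log2 fold change from 25 to 50 mM (vertical) against that from 5 to 50 mM (horizontal) for genes tested in both comparisons; blue points were called from 5 mM and the square marks TAGLN, called in both. CTGF, ANKRD1 and EDN1 lay to the right of 1 on the horizontal axis, PRSS35 at 1.74.

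The last comparison set the 25 mM against the 5 mM cultures, which differ in how they were kept. MMP1 (Entrez Gene 4312, chromosome 11, 102789919 to 102798160), a collagenase, was at 0.106 ± 0.0386 RPKM at 25 mM, under the 3-read floor of a 1 kb gene, and at 45.8 ± 3.02 RPKM at 5 mM. SFRP1, a Wnt antagonist, was at 1.0 ± 0.293 against 39.2 ± 4.15 RPKM, IL24 at 2.77 ± 0.415 against 67.4 ± 6.1 RPKM, and ITGA2, a collagen-binding integrin, at 2.18 ± 0.142 against 53.6 ± 2.32 RPKM. Higher at 25 mM were LIN7A, a cell polarity protein, at 14.7 ± 0.0333 against 1.44 ± 0.169 RPKM, and GFRA1, a receptor subunit for GDNF, at 23.8 ± 4.43 against 3.23 ± 0.091 RPKM. COL8A1, CCDC80 and the oxytocin receptor OXTR were 3.03-, 2.95- and 2.92-fold higher at 25 mM, and ARHGDIB 16.4-fold lower. AKR1B1 was 4.1-fold lower at 25 mM (144 ± 7.75 against 592 ± 47.4 RPKM) and TXNIP 1.82-fold lower.

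ERK output genes were lower at 25 mM: of 22 tested, 2 were higher, 17 lower and 3 did not pass, with the same numbers adjusted over the list alone (median log2 difference -0.81, adjusted p = 1.07e-05; adjusted p = 0.185 with an estimated correlation). DUSP6 was 3.9-fold lower (4.25 ± 0.789 against 19.5 ± 3.47 RPKM) and SPRY4 3.35-fold lower. In the YAP1/TAZ target signature 12 of 22 were higher, 3 lower and 7 did not pass, with 13 higher and 3 lower adjusted over the list alone (median log2 difference 0.32, adjusted p = 0.0023; adjusted p = 0.185 with an estimated correlation). The members moved apart: TGFB2 was 1.93-fold and CTGF 1.22-fold higher at 25 mM, while ANKRD1 was 5.44-fold lower. YAP1 was 1.20-fold higher (adjusted p = 0.00459) and WWTR1 1.17-fold lower (adjusted p = 0.0228) at 25 mM. In the Hippo pathway list 15 of 27 were higher and 2 lower, over all genes tested and adjusted over the list alone (median log2 difference 0.27, adjusted p = 0.00571; adjusted p = 0.185 with an estimated correlation). All 19 interferon response genes were lower at 25 mM, over all genes tested and adjusted over the list alone (median log2 difference -2.54, adjusted p = 4.04e-11; adjusted p = 0.273 with an estimated correlation). Glycolysis genes were lower, 16 of 22 over all genes tested, with 1 higher and 18 lower adjusted over the list alone (median log2 difference -0.34, adjusted p = 3.9e-05; adjusted p = 0.185 with an estimated correlation).

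By limma 2032 genes were higher and 2639 lower at 25 mM, out of 11941 tested, and 40 of the higher and 569 of the lower differed by at least 2-fold. The balance of directions followed the scaling, with 2648 higher and 2068 lower after quantile normalization and 3906 higher and 2327 lower after the GC correction. Replication-dependent histones, a list set to watch library quality because their transcripts mostly lack poly(A) tails, were lower at 25 mM, 12 of 13 over all genes tested and 12 adjusted over the list alone (median log2 difference -1.51, adjusted p = 2.35e-07; adjusted p = 0.185 with an estimated correlation). The list differences given for these cultures stand beside this one, and a difference in RNA or library quality was not excluded. The comparison cannot separate glucose from culture, batch or table, since the groups with 25 mM and 5 mM as their starting glucose lie in separate tables and no library links them.

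Libraries of a group differed by GC content. In 5 mM replicate 1 the bin of genes richest in GC lay at a median of -0.41 log2 against replicate 3, and in 25 to 50 mM replicate 3 at -0.30 against replicate 2. The same bin differed by 0.08 between the 25 mM libraries and by -0.10 between the 5 to 50 mM libraries.

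**Figure D4:**
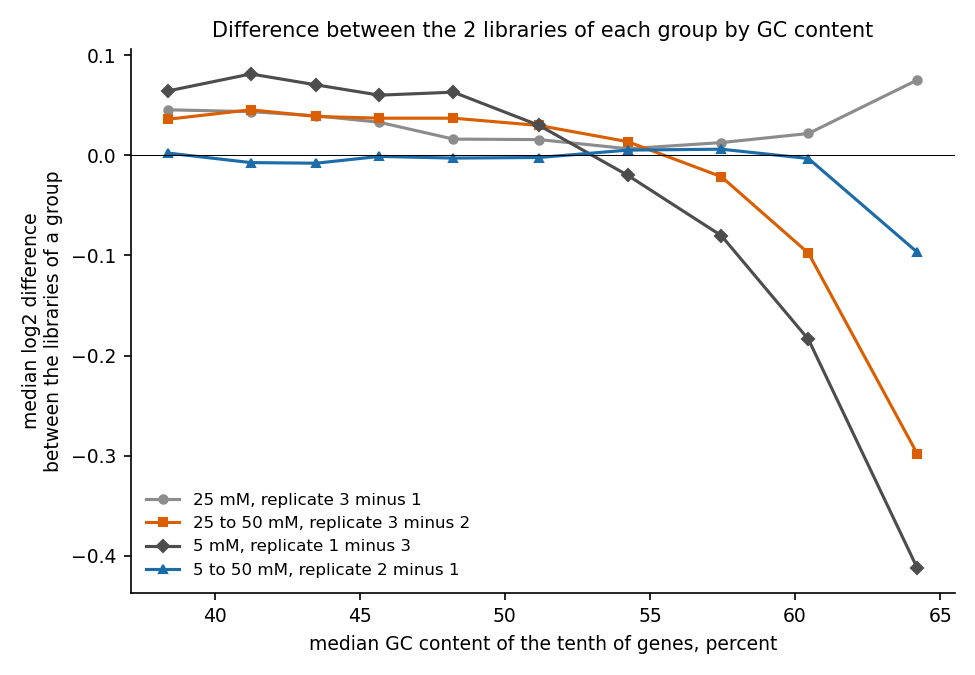
Median log2 difference between the 2 libraries of each group (vertical) in 10 bins of genes ordered by transcript GC content in percent (horizontal). The curve of 5 mM replicate 1 ends at -0.41 and that of 25 to 50 mM replicate 3 at -0.30.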

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

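The tests of drift, carry-over, GC bias, gene length, a persisting acute effect and a batch were chosen only after the result was seen. The tests of the difference between the responses and the repeats with an estimated correlation were planned.

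From 5 to 50 mM all 19 interferon response genes had higher fitted values, and in the difference between the responses the list lay at a median of -0.83 log2 (adjusted p = 2.6e-15; adjusted p = 0.328 with an estimated correlation). The GC trend of 5 mM replicate 1 was argued against, since the list's median change was 0.50 after GC correction and 0.48 before it. A drift of interferon gene levels between libraries could shape the difference between the responses: the list lay 0.525 log2 higher in 25 mM replicate 3 than in replicate 1, and the difference was -0.479 without replicate 3. In the 2 groups of the rise itself the libraries differed by 0.018 at 5 mM and 0.08 at 5 to 50 mM, and at 25 to 50 mM by -0.226, so for the rise from 5 mM a drift stays open but was not seen between its libraries. Carry-over of 5 mM material into that library was argued against: the other genes at least 4-fold higher at 5 mM had a median mixed-in share of 1.79%, against 8.27% for interferon genes. The hypothesis that glucose itself acts on interferon genes in cells kept at 5 mM remains open, and the list's median stayed at 0.478 log2 or more with 1 library left out.

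In 25 to 50 mM replicate 3 and 5 mM replicate 1 the GC-rich transcripts were low. The within-group difference had a Spearman correlation across genes of -0.426 with GC content in the weaker of the 2 groups. That value restates the pattern by which the libraries were picked, so it cannot test a GC bias of the library as its cause. Gene length as the source of this trend was argued against, since the correlation with GC content given length was -0.425 and -0.558 in the 2 groups. Whether length adds a trend of its own is open, with a partial correlation given GC content of 0.302 in the 5 mM group and 0.07 in the 25 to 50 mM group. A difference shared by both libraries beyond GC content fits. Their within-group differences kept a Spearman correlation of 0.325 across genes after GC correction, against 0.483 before it, though genes are not independent replicates.

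The cultures kept at 25 and at 5 mM differed in 4671 genes. An acute effect of glucose that persists could give such a difference, but with split controls the Spearman correlation across genes with the change from 5 to 50 mM was 0.06 with 1 control library and -0.07 with the other. A batch or culture difference between the 2 tables would also give it, and the first principal component, which separated the tables, held 80.9% of the variance. Neither explanation can be told apart from an effect of the maintained glucose, because the design joins table, culture and glucose.

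Single genes differed between the responses by -1.97 log2 for PRSS35, -1.50 for RANBP3L and 0.73 for SERPINB2, each with an adjusted p of 0.0361. With a replicate block 0 genes passed. The means of RANBP3L at 25 mM and 25 to 50 mM lay under the 3-read floor of a 1 kb gene.

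Cholesterol synthesis genes differed by a median of -0.22 log2 (adjusted p = 1.16e-09; adjusted p = 0.0639 with an estimated correlation). Cytosolic ribosomal proteins differed by 0.069 (adjusted p = 0.000224; adjusted p = 0.328 with an estimated correlation). Targets of p53 differed by 0.18 (adjusted p = 0.000757; adjusted p = 0.328 with an estimated correlation). NF-kB and cytokine response genes differed by -0.19 (adjusted p = 0.00152; adjusted p = 0.524 with an estimated correlation). Glycolysis genes differed by 0.094 (adjusted p = 0.00295; adjusted p = 0.312 with an estimated correlation). Cardiac stress and hypertrophy markers differed by -0.39 (adjusted p = 0.00467; adjusted p = 0.312 with an estimated correlation). The YAP1/TAZ target signature differed by -0.13 (adjusted p = 0.0097; adjusted p = 0.328 with an estimated correlation). Hypoxia genes differed by 0.078 (adjusted p = 0.026; adjusted p = 0.328 with an estimated correlation). Genes of G1/S and DNA replication differed by 0.055 (adjusted p = 0.0497; adjusted p = 0.59 with an estimated correlation). With neither GC-trend library the calls of 4 lists were lost: NF-kB and cytokine response genes (adjusted p = 0.535), cardiac stress markers and the YAP1/TAZ signature (each adjusted p = 0.162), and G1/S genes (adjusted p = 0.641).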

How the results depend on the processing

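Chosen only after the result was seen were the GC correction, voom on recovered reads and the joint fit with a replicate block. So were the fits with neither GC-trend library and the 4 control libraries alone. The same holds for the settings for lists and named genes outside the rises to 50 mM, apart from the estimated correlation. The other settings were planned. The planned count tests were not run. The plan called for them if whole reads could be recovered, and they were, but the rules of this work allow count tools for no RPKM values; voom stood in for them, and what they would have called is not known. With the replicate number as a block in the joint fit of all 8 libraries (replicate block), limma called 0 genes from 25 to 50 mM, 0 from 5 to 50 mM, 0 for the difference between the responses and 3456 for 25 mM against 5 mM. The blocked fit had 2 residual degrees of freedom against 4 and a median SE of 0.107 against 0.083 for each rise. The log2 change of CTGF from 5 to 50 mM was 1.107 with the block and 1.082 without it, and that of TAGLN from 25 to 50 mM 0.699 and 0.714. For 25 mM against 5 mM a replicate block over the 4 control libraries called 4622 genes.

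From 25 to 50 mM, 1 gene passed. The count was 0 with no filter, 0 without trend, 0 with a fold of at least 2, 2 with quantile normalization, 2 at an adjusted p under 0.1, 3 with robust estimation, 4 in the joint fit, 7 by voom and 12 with the GC correction. With 1 library left out it ran from 0 (without 25 mM replicate 1) to 777 (without 25 to 50 mM replicate 2). From 5 to 50 mM, 39 genes passed. The count was 0 with no filter, 0 without trend, 8 with a fold of at least 2, 59 with median centring, 61 with quantile normalization, 75 at an adjusted p under 0.1, 130 (105 up, 25 down) in the joint fit and 169 (147 up, 22 down) with the GC correction. With 1 library left out it ran from 0 (without 5 to 50 mM replicate 2) to 805 (without 5 mM replicate 1). The cause was not tested.

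For the difference between the responses 3 genes passed. The count was 0 with a pseudocount of 0.1 or 0.5, 0 with a mean of at least 5 RPKM, 0 by voom, 0 with neither GC-trend library, 1 with no filter, 1 without trend, 5 with median centring and 5 with the GC correction. With 1 library left out it ran from 0 (without 25 mM replicate 3) to 6 (without 25 mM replicate 1). For 25 mM against 5 mM, 609 of 4671 genes had a fold of at least 2, and with 1 library left out the count ran from 3024 (without 25 mM replicate 1) to 4769. The cause was not tested.

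With an estimated correlation 0 lists passed from 25 to 50 mM, 0 from 5 to 50 mM, 0 for the difference between the responses and 0 for 25 mM against 5 mM. That setting also uses the few residual degrees of freedom of each fit, so these losses are not evidence of correlation among members. With neither GC-trend library 6 lists (4 up, 2 down) passed, in place of 10 (5 up, 5 down), for the difference between the responses. With 1 library left out the lists passing ran from 4 (without 25 to 50 mM replicate 2) to 11, from 9 (without 5 mM replicate 1) to 13, from 5 (without 5 mM replicate 3) to 12 and from 14 to 15, in that order. The correlation of the responses across genes ran from -0.078 (without 5 mM replicate 3) to 0.541 (without 5 mM replicate 1). The GC trends of 5 mM replicate 1 and 25 to 50 mM replicate 3 would move it in these directions. The cause was not tested.

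Genes near no change turned sign. From 25 to 50 mM, YAP1 was at 0.019 with median centring, 0.008 with quantile normalization and 0.017 with the GC correction, AMOTL2 at 0.085 with the GC correction, MAPK3 at 0.013 with the GC correction and SPRY4 at 0.018 with quantile normalization. From 5 to 50 mM, MAPK3 was at 0.001 with the GC correction. With 1 library left out, log2 changes from 25 to 50 mM ran from -0.054 to 0.033 for YAP1, -0.286 to 0.021 for DUSP6, -0.237 to 0.091 for SPRY4, -0.049 to 0.164 for SLC5A3, -0.026 to 0.163 for CNN1 and -0.056 to 0.158 for SMTN. From 5 to 50 mM they ran from -0.036 to 0.283 for AMOTL2, -0.072 to 0.023 for MAPK3, -0.326 to 0.021 for DUSP6, -0.013 to 0.346 for SPRY4, -0.031 to 0.178 for TXNIP, -0.045 to 0.256 for SMTN and -0.004 to 0.078 for ACTA2.

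Over all settings, values of named genes were unchanged in call and direction in 904 cases, gained a call in 72, lost one in 65 and turned sign in 23. List calls were unchanged in 360 cases and lost in 93.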

Other observations

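The list tests of this part and their repeats with an estimated correlation were planned. Between the cultures kept at 25 and at 5 mM, lists not described above differed as well. NF-kB and cytokine response genes were lower at 25 mM, 15 of 18 over all genes tested and 15 adjusted over the list alone (median log2 difference -1.45, adjusted p = 2.35e-07; adjusted p = 0.21 with an estimated correlation). IL6 was at 7.73 ± 0.557 RPKM at 25 mM and 48.3 ± 3.2 RPKM at 5 mM (SD, n = 2), a fold of 5.65, and CCL2 was 5.21-fold lower at 25 mM. Targets of p53 were lower, 15 of 20 over all genes tested, with 1 higher and 16 lower adjusted over the list alone (median log2 difference -0.58, adjusted p = 0.000202; adjusted p = 0.19 with an estimated correlation). MDM2 was 1.56-fold lower at 25 mM.

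ATF4 targets of the integrated stress response were lower at 25 mM, 16 of 24 with 1 higher over all genes tested, and 17 with 1 higher adjusted over the list alone (median log2 difference -0.51, adjusted p = 8.48e-05; adjusted p = 0.185 with an estimated correlation). G2/M cell cycle genes were higher at 25 mM, 12 of 24 over all genes tested and 13 adjusted over the list alone (median log2 difference 0.23, adjusted p = 0.000282; adjusted p = 0.358 with an estimated correlation). Cytosolic ribosomal proteins, like histones a list set to watch library quality, were higher, 23 of 46 with 1 lower over all genes tested, and 24 with 1 lower adjusted over the list alone (median log2 difference 0.16, adjusted p = 1.07e-05; adjusted p = 0.185 with an estimated correlation). ACTA2 was 3.08-fold lower at 25 mM, TNC 3.2-fold lower and CNN1 2.18-fold higher.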
